A study of Mus musculus with 6 samples.

How the data were processed

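Gene expression was measured by RNA sequencing of inguinal white adipose tissue from 6 mice, 3 WT and 3 Hsp20 knockout. Per the labels' protocols, the mice were not fasted, RNA was isolated with a kit for lipid-rich tissue, and standard Illumina libraries were made. The submitters' processing notes name bcl2fastq, CASAVA 1.8, TopHat and DESeq and the builds mm10 and GRCm38. The read counter, gene annotation and strand setting are not given in the sources used here, so overlapping and antisense genes, such as Lin37, which overlaps the end of Hspb6 by 3 bases, may share reads. The authors deposited whole-number read counts per gene, not normalized, with 1 column per mouse and no pooling.

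Columns were matched to samples by the sample names in the labels. Of 24415 gene IDs, 24334 were matched to symbols through a RefSeq table of GRCm38.p6, and the other 81 held between 1.30% and 5.74% of the counts of a library. Of these, 1 ID alone took 5.02% of WT replicate 1 and between 0.881% and 2.20% of the other libraries. Library totals ran from 14078936 to 32648746 counts, and the smallest library limits the precision of low genes. No pair of libraries of a group agreed within sampling noise (chi-square per degree of freedom of at least 18.1). The first principal component of log2 CPM held 51.6% of the variance and separated the groups. The library labelled knockout replicate 1 lay nearest to WT along it, at 17.3 against 37.0 and 35.0.

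The test was edgeR 4.0.16 in R 4.3.3: filterByExpr by genotype (minimum count 10, minimum total 15), TMM normalization, and the quasi-likelihood F test with genotype as the only term, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 change is the one implied by the F statistic, and CPM uses TMM-scaled library sizes. The biological coefficient of variation was 14.8%. Gene lists, 31 in all, were tested with limma 3.58.1 camera on log2 CPM (prior count 2, preset correlation 0.01), with an estimated correlation, and with fry. Camera called 18 lists at the preset correlation and 0 with an estimated one, where 1 list had an unadjusted p under 0.05, and fry called 8 lists by direction and 22 for changes in either direction. Members were counted over all genes and adjusted over the list alone. Calls near Hspb6 were tested with Fisher's exact test against tested genes elsewhere.

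The sample groups, designs, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Hspb6, the 12 genes with the largest rise and the 12 with the largest fall among calls with a mean of at least 1 CPM and no overlap of the groups, up to 4 members per list, and 8 genes always. Some genes that the rule takes are not reported here. Other genes are said to be chosen after their values were seen. Alternatives were DESeq2 size factors, upper quartile normalization, other filters and thresholds, DESeq2 1.42.0, limma-voom, robust dispersions, a replicate block, leaving out each library and, added later, thinning to the smallest library and a 1 Mb window. On counts simulated from the libraries' means, sizes and dispersions (15865 genes tested), the test recovered 32.8% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 95.5% of those changed 4-fold. In that simulation 12.3% of 155 calls were of unchanged genes, above the nominal rate, and camera called 3 of 3 lists changed 1.3-fold and 0 of 17 unchanged ones, with independent genes. Figures were drawn with matplotlib.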

Results

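RNA from inguinal white adipose tissue, a subcutaneous fat depot that can take up features of brown fat, was sequenced from 6 mice aged 12 weeks on a C57BL/6 background. WT mice and Hsp20 knockout mice gave 3 libraries each, 1 per mouse. Hsp20 is the small heat shock protein encoded by Hspb6. WT replicates 1 to 3 held 26146472, 29809479 and 32648746 counts, and the libraries labelled knockout replicates 1 to 3 held 27937060, 21294967 and 14078936. The series asks how expression in this depot differs when Hsp20 is lacking. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were counted in all 6 libraries (Ddx3y from 1480 to 3368 counts), and Xist had between 5 and 13 counts.

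Hspb6, the targeted gene (gene ID 243912, chromosome 7, 30552535 to 30555443 on GRCm38, plus strand, 3 coding-transcript exons), had 325, 289 and 296 counts in WT replicates 1 to 3. The library labelled Hsp20 KO replicate 1 had 245 counts, and those labelled replicates 2 and 3 had 33 and 53. As CPM, counts scaled to a common library total, these were 12.6, 9.43 and 8.95 in WT against 8.86, 1.51 and 3.94, so the library labelled replicate 1 lay 0.194 of the way from the WT mean to the mean of the other labelled knockout libraries. Mean Hspb6 was 10.3 ± 1.99 CPM in WT and 4.77 ± 3.74 CPM in the libraries labelled knockout (SD, n = 3 each), a log2 change of -1.08 ± 0.51 (SE) that did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.227). Without the library labelled replicate 1 the log2 change of Hspb6 was -1.99 (edgeR adjusted p = 0.0221). The part of the gene that the knockout allele lacks is not given in the sources used here, so counts over the whole gene may include parts that the allele keeps. Every direction below compares the libraries labelled knockout, this one included, with WT.

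**Figure D1:**
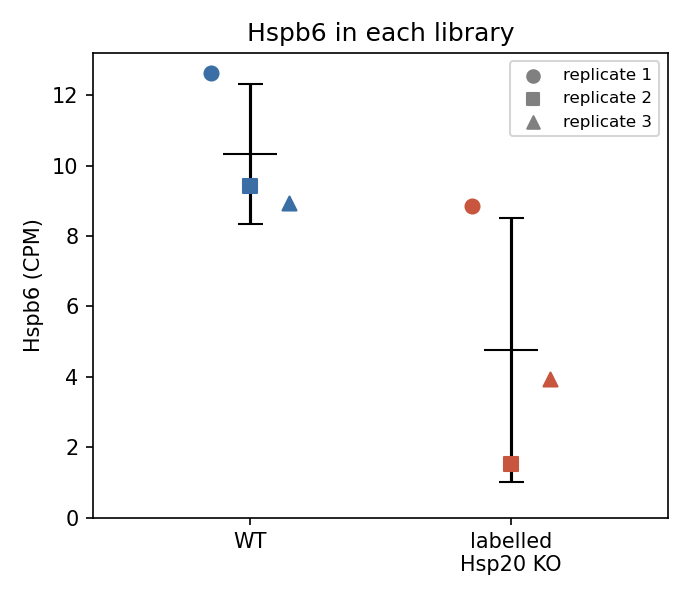
Hspb6 in CPM (vertical axis, from 0) in the 3 WT libraries (blue) and the 3 libraries labelled Hsp20 KO (red); marker shapes give the replicate, and horizontal lines with bars give the mean and SD. The library labelled Hsp20 KO replicate 1, at 8.86 CPM, lies beside the lowest WT library at 8.95 CPM.

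Many thermogenic, lipogenic and mitochondrial genes rose in the libraries labelled knockout, most transcripts of the blood list fell, and genes of the circadian clock changed in both directions. Of the 31 gene lists, 18 passed limma camera with its preset correlation and 0 with an estimated one. Fry by direction passed the thermogenic, lipogenesis, citric acid cycle, oxidative phosphorylation, clock, epidermis, blood and smooth muscle lists (adjusted p from 0.0118 to 0.0368). It did not pass the remaining lists, among them fatty acid oxidation and cholesterol synthesis (both fry adjusted p = 0.052), unfolded protein response (0.143) and macrophage (0.154). Ucp1, the uncoupling protein of thermogenic fat, rose from 1.82 ± 0.79 to 164 ± 144 CPM (SD, n = 3 each), with 19.1, 165 and 308 CPM in the libraries labelled replicates 1 to 3 (log2 change 6.51 ± 1.03 SE, edgeR quasi-likelihood adjusted p = 0.016). Ctse, the aspartic protease cathepsin E, rose from 2.34 ± 0.436 to 46.9 ± 7.94 CPM. Ffar1, a receptor for free fatty acids, fell from 3.85 ± 0.545 to 0.0514 ± 0.0544 CPM, and Cyp1a1, a cytochrome P450 induced through the aryl hydrocarbon receptor, fell from 10.4 ± 7.48 to 0.439 ± 0.399 CPM. Of 15994 genes tested with edgeR's quasi-likelihood test, 676 were higher and 547 lower at a Benjamini-Hochberg adjusted p under 0.05, and 222 and 150 of these changed at least 2-fold. Over all tested genes, called or not, the groups did not overlap for 5195, 32.5%, against a 10% chance share for 3 against 3. The 10% is the expectation for a single gene. Genes vary together, so the share over genes in any grouping can lie far from it, and the comparison is no test of chance. Without the library labelled knockout replicate 1 the test called 941 genes higher and 730 lower, without WT replicate 1, 2 or 3 it called 325 and 329, 79 and 58, or 75 and 53, and without the one labelled knockout replicate 2 or 3 it called 325 and 287 or 327 and 266.

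Among genes named by size of change, Mcpt2, a mast cell protease, had 3 counts over the WT libraries and 431 over those labelled knockout. Scaled to library size this is a ratio of 204 (95% counting interval 69.4 to 994). That interval sums the mice of a group and leaves out the spread between them. The libraries labelled knockout replicates 1 to 3 had 266, 119 and 46 counts. The edgeR fit gave a fold of 164 (adjusted p = 0.00411). Elovl3, an elongase of very long chain fatty acids, rose 34.2-fold, 6330403K07Rik 33.02-fold, Cpn2 16.8-fold, Gchfr 15.5-fold, Rufy4 14.7-fold, Fabp3 13.6-fold and Slc25a48 12.8-fold. Serpina1b, which can share reads with near-identical copies and is therefore uncertain, rose 14.1-fold. Mrgprg fell by 5.39 on the log2 scale, Ptx3, a pentraxin of inflamed tissue, by 3.98, Gm4956 by 3.69, 2810459M11Rik by 3.19, Gm4567 by 2.91, Cyp2f2 by 2.89 and Gm3893 by 2.85. Cyp2f2 and Gm4567 lie on chromosome 7 at -3427 and -7837 kb from Hspb6, inside the 10 Mb window tested below, as does Ffar1. Ptx3 ranged from 3.26 to 32.3 CPM among the WT libraries. The Y-linked Rbmy, Gm21677 and Gm21708 fell by 4.51, 4.43 and 4.40 on the log2 scale, and since they are near-identical copies that can share reads, their changes are uncertain. With upper quartile normalization Cyp2f2 and Gm4567 did not pass (both adjusted p = 0.0504), and with limma-voom Ucp1 (adjusted p = 0.0782), Fabp3 (0.101) and Ptx3 (0.164) did not pass.

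Most measured thermogenic genes rose: 14 of 21 members of the brown fat list rose and 0 fell, or 15 and 0 adjusted over the list alone, with a median log2 change of 1.53. Ppargc1a and Prdm16, picked after their values were seen, were among the 7 that did not pass (log2 change 0.016 and 0.21, edgeR adjusted p = 0.983 and 0.531). Cidea, a lipid droplet protein abundant in brown fat, rose from 37.8 ± 5.71 to 219 ± 83.5 CPM (edgeR adjusted p = 0.00638), and Cpt1b, which admits long-chain fatty acids to mitochondria, rose from 9.93 ± 1.25 to 91.4 ± 49.0 CPM. Pank1, a pantothenate kinase of coenzyme A synthesis, rose from 10.3 ± 1.27 to 40.4 ± 10.01 CPM, and Cox7a1, a cytochrome c oxidase subunit, from 2.19 ± 0.661 to 16.0 ± 7.61 CPM (edgeR adjusted p = 0.0126). Cox7a1 lies at -369 kb from Hspb6 on chromosome 7. The library labelled knockout replicate 1 had the smallest thermogenic excess, a list median 0.966 above the WT mean on the log2 scale, against 2.04 and 1.87 in replicates 2 and 3. The list passed limma camera with its preset correlation (adjusted p = 1.83e-09) and not with an estimated one (adjusted p = 0.429 with an estimated correlation). Limma-voom called 8 of the 21. Without WT replicate 2 or 3, 3 of 22 thermogenic genes were called, without WT replicate 1 or the library labelled knockout replicate 2, 8, and without replicate 3, 7. Beige markers did not pass (median -0.08, limma camera adjusted p = 0.41), with 0 of 11 higher and 1 lower by either adjustment, Klhl13. This gene was not called without WT replicate 2 or 3 (edgeR, 0 beige markers called and 2 lower at an unadjusted p under 0.05).

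Lipogenic enzymes rose as well: 13 of 21 rose and 0 fell, or 16 and 0 adjusted over the list alone, with a median log2 change of 1.03 (limma camera adjusted p = 3.48e-10; adjusted p = 0.429 with an estimated correlation). Acly, which makes cytosolic acetyl-CoA, rose from 624 ± 77.4 to 2543 ± 639 CPM, and Acacb, an acetyl-CoA carboxylase, rose from 254 ± 38.9 to 691 ± 87.9 CPM. Slc25a1, the mitochondrial citrate carrier, rose 2.87-fold and Acss2, an acetyl-CoA synthetase, 2.80-fold. Of the 21 lipogenic genes 4 were called without WT replicate 2 or 3. Of 23 cholesterol synthesis genes 4 rose, Fdft1, Nsdhl, Lss and Fdps, between 1.59-fold and 1.85-fold, and 0 fell (8 and 0 adjusted over the list alone; limma camera adjusted p = 0.00182, or adjusted p = 0.429 with an estimated correlation). Leaving out WT replicate 2 or 3 or the library labelled knockout replicate 2 or 3 left 1 cholesterol gene called, and leaving out WT replicate 1 left 2. Leaving out the one labelled knockout replicate 1 gave 8. Adipocyte identity genes did not pass as a group (median 0.11, limma camera adjusted p = 0.326). Among them 5 of 30 rose and 1 fell (6 and 2 adjusted over the list alone), and Gpd1, Agpat2, Dgat2 and Fabp5, enzymes and a carrier of lipid storage, rose between 1.85-fold and 2.47-fold. Without WT replicate 3 edgeR called 0 of the 30, with 6 higher and 2 lower at an unadjusted p under 0.05. It called 1 higher and 0 lower without WT replicate 2, 3 and 1 without WT replicate 1, and 6 and 4, 5 and 0, or 3 and 0 without the libraries labelled knockout replicate 1, 2 or 3. Pparg, the transcription factor that drives fat cell differentiation, had a log2 change of 0.24 ± 0.15 (edgeR adjusted p = 0.333), Adipoq of -0.31 ± 0.18 (0.308), Lep of -0.12 ± 0.19 (0.737) and Slc2a4, the insulin-regulated glucose carrier, of 0.38 ± 0.12 (0.105). In the lipolysis list Prkaca, Adora1 and Prkar2b rose, 3 of 20, and 0 fell (4 and 1 adjusted over the list alone; limma camera adjusted p = 0.167). Without WT replicate 1, 2 or 3 edgeR called 0 of the 20, with 5, 4 or 5 higher at an unadjusted p under 0.05.

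Most members of the mitochondrial lists had a positive log2 change, called or not: 66 of 67 for oxidative phosphorylation, 22 of 22 for the citric acid cycle and 22 of 24 for fatty acid oxidation. Of 67 oxidative phosphorylation genes 42 rose and 0 fell, or 63 and 0 adjusted over the list alone, with a median log2 change of 0.53 (limma camera adjusted p = 1.34e-23; adjusted p = 0.447 with an estimated correlation). Uqcrfs1, the iron-sulfur subunit of complex III, rose from 108 ± 4.08 to 171 ± 17.5 CPM, and Cox5b, Ndufab1 and Atp5k rose 1.505-fold, 1.68-fold and 1.37-fold. In the citric acid cycle list 17 of 22 rose and 0 fell, or 22 and 0 adjusted over the list alone (median 0.62, limma camera adjusted p = 2.01e-13; adjusted p = 0.429 with an estimated correlation). Pdha1, Pdhb and Dlat, parts of the pyruvate dehydrogenase complex, rose 2.19-fold, 2.18-fold and 2.16-fold. In the fatty acid oxidation list 13 of 24 rose and 0 fell, or 17 and 0 adjusted over the list alone (median 0.67, limma camera adjusted p = 8.37e-09; adjusted p = 0.468 with an estimated correlation). Hadha and Acadvl, enzymes of beta-oxidation, rose 2.29-fold and 2.13-fold, and Acot2, a mitochondrial thioesterase, 1.82-fold. These counts fell when most single libraries were left out. Without WT replicate 2 or 3 edgeR called 0 members of the 3 lists, with 60 or 61 oxidative phosphorylation genes, 21 or 21 citric acid cycle genes and 17 or 16 fatty acid oxidation genes higher at an unadjusted p under 0.05. For the 3 lists in that order it called 10, 5 and 5 without WT replicate 1, 11, 5 and 5 without the library labelled knockout replicate 2, 14, 6 and 5 without replicate 3, and 59, 21 and 15 without replicate 1. The list medians without WT replicate 2 were 0.52, 0.60 and 0.71. Each list still passed limma camera at its preset correlation (adjusted p from 1.65e-21 to 8.43e-09). That setting takes genes as nearly independent, though the lists' estimated correlations over all libraries were 0.732, 0.678 and 0.578. These p-values do not measure the spread between mice, and no estimated correlation was run with a library left out.

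**Figure D2:**
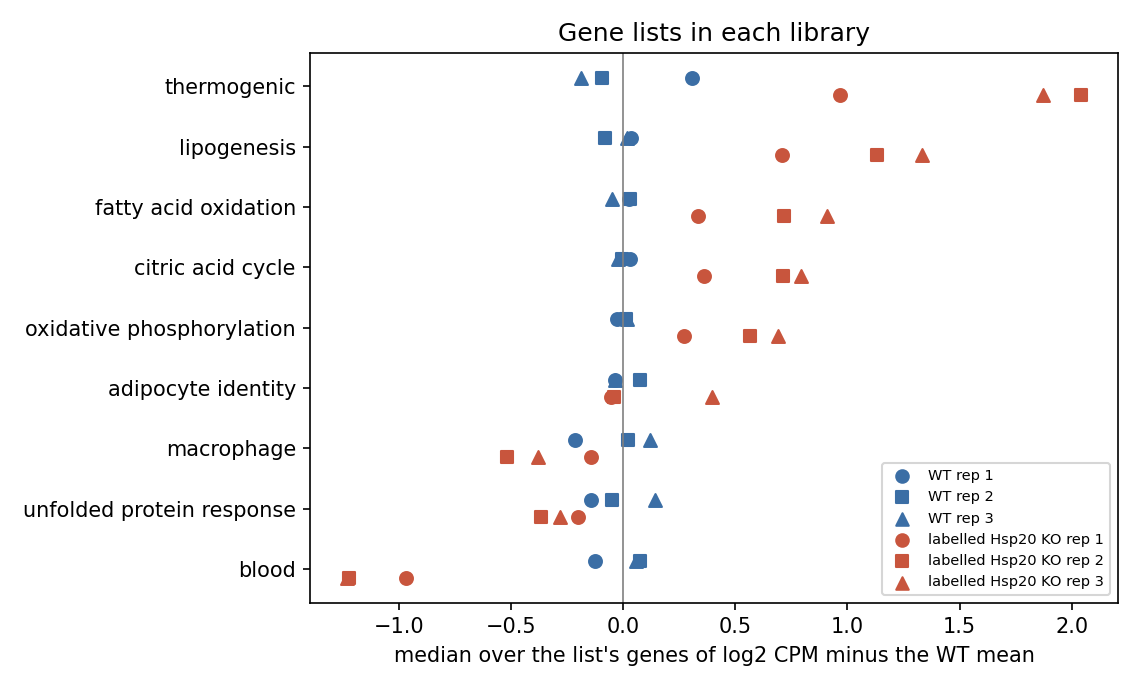
Median over each list's tested genes of log2 CPM minus the WT mean (horizontal axis) for 9 gene lists (vertical axis) in the WT libraries (blue) and those labelled Hsp20 KO (red), with marker shapes for the replicate. In the thermogenic list the libraries labelled knockout lie at 0.966, 2.04 and 1.87, and in the blood list at -0.968, -1.22 and -1.23.

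**Figure D3:**
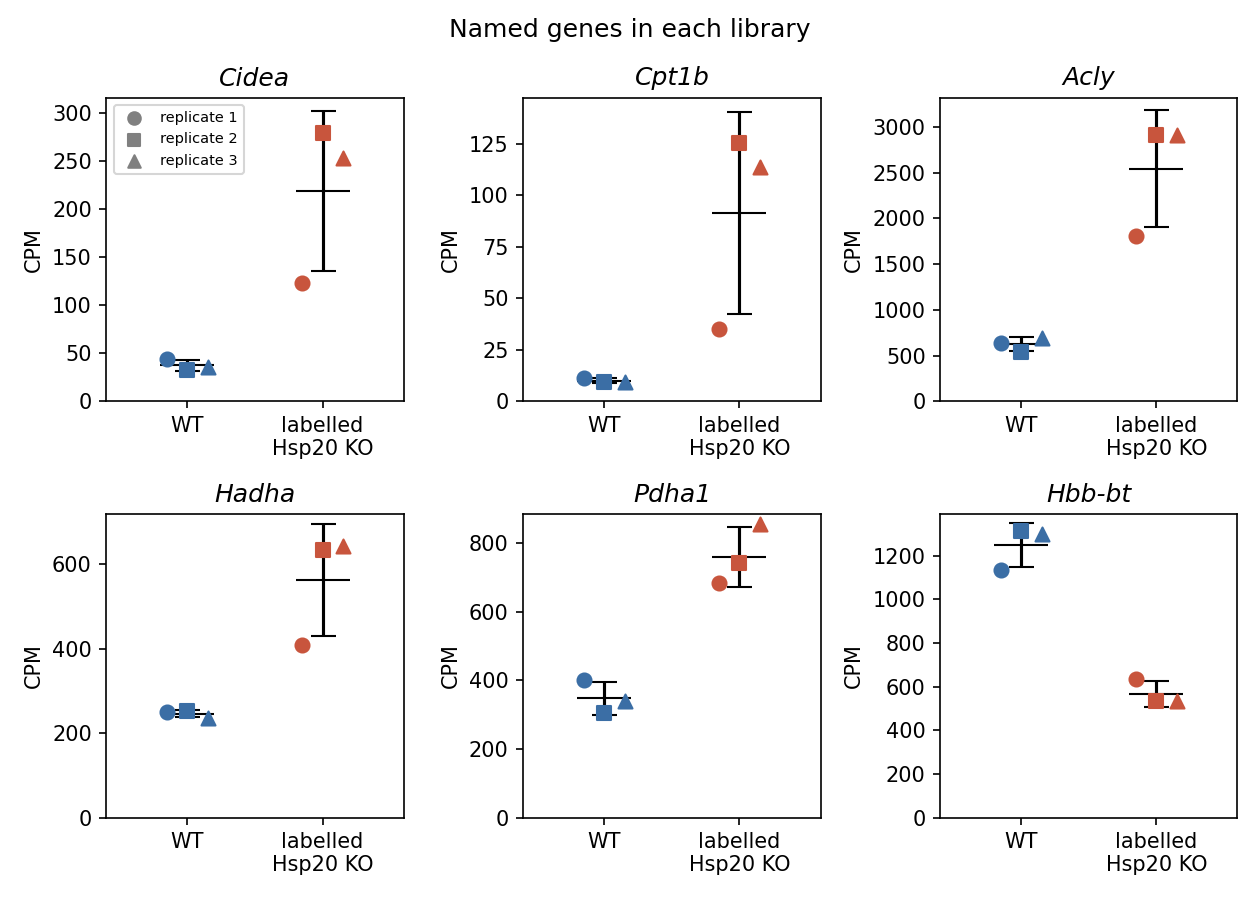
CPM (vertical axes, from 0) of Cidea, Cpt1b, Acly, Hadha, Pdha1 and Hbb-bt in the 3 WT libraries (blue) and the 3 libraries labelled Hsp20 KO (red), with marker shapes for the replicate and lines with bars for the mean and SD. In each panel the groups do not overlap, and for Cidea the libraries labelled knockout lie at 124, 280 and 253 CPM.

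Circadian clock genes changed in both directions: 11 of 19 rose and 4 fell, or 12 and 4 adjusted over the list alone. Dbp, a clock-controlled transcription factor, rose from 23.9 ± 6.48 to 157 ± 26.2 CPM (edgeR adjusted p = 0.00212), and Bhlhe41, a repressor of clock transcription, rose from 8.93 ± 1.99 to 57.1 ± 11.5 CPM. Ciart and Per3 rose 3.86-fold and 3.23-fold. The 4 that fell, identified after their values were seen, were Arntl (log2 change -1.32 ± 0.16 SE), Npas2 (-2.75 ± 0.30), Clock (-0.64 ± 0.10) and Nfil3 (-1.50 ± 0.35). The list passed limma camera as higher (adjusted p = 1.96e-04; adjusted p = 0.447 with an estimated correlation), and fry passed it for changes in either direction (adjusted p = 1.03e-04). Without WT replicate 3, 2 of the 19 fell. The time of day at which tissue was taken is not given in the sources used here.

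**Figure D4:**
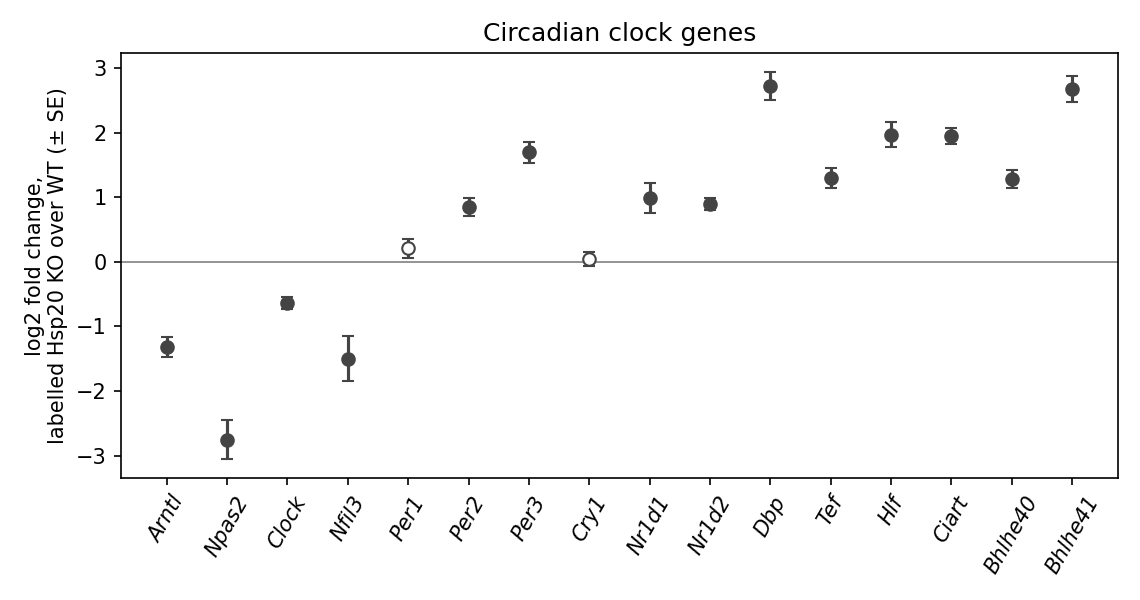
Log2 fold change of the libraries labelled Hsp20 KO over WT (vertical axis) with its SE (bars) for 16 circadian clock genes (horizontal axis); filled points passed an adjusted p of 0.05 and open points did not. Arntl, Npas2, Clock and Nfil3 lie below 0, and Dbp lies at 2.72.

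Of 24 genes of the unfolded protein response 0 rose and 6 fell, or 1 and 12 adjusted over the list alone (median -0.35, limma camera adjusted p = 0.00136; adjusted p = 0.633 with an estimated correlation). Calr and Hsp90b1, chaperones of the endoplasmic reticulum, fell by 0.49 and 0.50 on the log2 scale, and Dnajc3 and Edem1 by 0.45 and 0.39. Without WT replicate 2 or 3 edgeR called 0 of the 24, with 11 lower at an unadjusted p under 0.05. It called 1 lower without WT replicate 1 or the library labelled knockout replicate 2 or 3. It also called 1 higher without WT replicate 1, and 1 higher and 4 lower without the one labelled knockout replicate 1. Cytosolic and mitochondrial heat shock genes did not pass as a group (median 0.03, limma camera adjusted p = 0.614). Hspa9, the mitochondrial Hsp70, rose from 349 ± 10.4 to 460 ± 25.5 CPM, and it was the only call among 29 members, with 0 calls adjusted over the list alone. That call held only without the library labelled knockout replicate 1: without WT replicate 1, 2 or 3 or the one labelled knockout replicate 2 or 3 edgeR called 0 of the 29, with 1, 1, 4, 2 or 2 higher at an unadjusted p under 0.05. Fbxo4, a substrate receptor of a ubiquitin ligase, had a log2 change of 0.04 ± 0.12 (edgeR adjusted p = 0.869), and the ubiquitin list around PPARg had 0 calls among 14 members by either adjustment (limma camera adjusted p = 0.393). Insulin signalling did not pass (median -0.10, limma camera adjusted p = 0.645), with Mtor and Gys1 higher and Foxo1 and Socs3 lower among 24 members (3 and 2 adjusted over the list alone). Without WT replicate 2 or 3 or the library labelled knockout replicate 3 edgeR called 0 of the 24, with 4, 3 or 4 higher and 5, 4 or 3 lower at an unadjusted p under 0.05.

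Of 28 macrophage and inflammatory genes 0 rose and 4 fell, or 0 and 8 adjusted over the list alone (median -0.26, limma camera adjusted p = 1.22e-04; adjusted p = 0.633 with an estimated correlation). The chemokine Ccl2 fell from 20.2 ± 8.60 to 3.35 ± 0.733 CPM (edgeR adjusted p = 0.00776), Ccl9 from 157 ± 51.8 to 49.4 ± 12.9, Ccl6 from 192 ± 59.9 to 79.2 ± 22.3 and the cytokine Il1b from 7.34 ± 3.24 to 1.84 ± 0.527 CPM. Of the 28 macrophage genes 1 was called without WT replicate 2 or 3, and without the library labelled knockout replicate 1 or 3, 11 or 2 of 29. The groups overlapped in the macrophage list median. It lay -0.215, 0.023 and 0.118 from the WT mean in WT replicates 1 to 3. In the libraries labelled knockout replicates 1 to 3 it lay at -0.141, -0.518 and -0.381. Of 11 blood transcripts 7 fell and 0 rose, or 9 and 0 adjusted over the list alone (median -1.15, limma camera adjusted p = 1.83e-09; adjusted p = 0.429 with an estimated correlation). Hbb-bt fell from 1250 ± 98.7 to 569 ± 59.8 CPM and Hbb-bs from 1681 ± 145 to 760 ± 73.9 CPM; Hbb-b2 and Hbb-b1 repeat their counts, and Hba-a1 and Hba-a2 differ by 2 counts in all. The 7 are therefore not independent genes, and the list's count and test take these copies more than once. Interferon genes did not pass as a group (median -0.08, limma camera adjusted p = 0.201), while Rsad2 and Cxcl10 fell by 1.14 and 1.57 on the log2 scale, 2 of 30 by either adjustment. Only 1 interferon gene fell without WT replicate 3, and 1 rose without the library labelled knockout replicate 2. Immediate early genes had 1 of 23 higher, Nr4a1, and 3 lower, Fosl2, Nr4a3 and Klf6 (1 and 6 adjusted over the list alone; limma camera adjusted p = 0.0379, or adjusted p = 0.738 with an estimated correlation). That call ended without the library labelled knockout replicate 3 (adjusted p = 0.561) or WT replicate 3 (0.148). Without WT replicate 2 or 3 edgeR called 0 of the 23, with 7 or 6 lower at an unadjusted p under 0.05. It called 5 or 1 lower without the library labelled knockout replicate 1 or 3. In either direction it called 4 without WT replicate 1, and 6, 2 or 2 without the libraries labelled knockout replicate 1, 2 or 3.

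B cell genes of the lymph node that lies in this depot had a median of -0.25 and T cell genes of 0.25, with 0 of 19 and 0 of 20 passing by either adjustment (limma camera adjusted p = 0.00412 and 0.0454; adjusted p = 0.738 and 0.799 with an estimated correlation). Their members with the smallest p were Spib, Cd72 and Cxcr5 (edgeR adjusted p from 0.168 to 0.189) and Il7r, Cd4 and Cd5 (from 0.0677 to 0.123). The B cell call ended without the library labelled knockout replicate 1 (limma camera adjusted p = 0.115) or 3 (0.101), and the T cell call without WT replicate 1 (0.272) or 3 (0.0969) or the one labelled knockout replicate 1 (0.192) or 2 (0.692). Without the library labelled knockout replicate 2, 17 of 19 B cell genes fell (median -0.67, limma camera adjusted p = 3.8e-16), and without replicate 3, 3 of 20 T cell genes rose (median 0.40, limma camera adjusted p = 8.3e-07). Both camera values are at the preset correlation, while the lists' estimated correlations over all libraries were 0.946 and 0.866. Skeletal muscle genes had a median of -2.79 with 0 of 22 passing by either adjustment (limma camera adjusted p = 0.00357; adjusted p = 0.738 with an estimated correlation). WT replicate 1 carried most of that signal, with a muscle list median 2.28 above the WT mean against -1.89 and -0.51 in WT replicates 2 and 3, and without it the muscle call ended (adjusted p = 0.0678). Ttn, Atp2a1 and Myh1 had 59.5, 160 and 71.1 CPM in WT replicate 1. Smooth muscle genes Lmod1 and Cnn1 fell, 2 of 14 by either adjustment (limma camera adjusted p = 0.00462; adjusted p = 0.429 with an estimated correlation). These calls were lost without WT replicate 1, 2 or 3, where edgeR called 0 of the 14, with 5, 3 or 3 lower at an unadjusted p under 0.05. Leaving out any 1 library labelled knockout left 1 lower, with 1 higher without replicate 1. Progenitor genes had 0 calls of 20 by either adjustment (limma camera adjusted p = 0.037, lost without WT replicate 2 at 0.0646, WT replicate 3 at 0.0659, or the libraries labelled knockout replicate 2 at 0.246 and replicate 3 at 0.0678; adjusted p = 0.633 with an estimated correlation); Anxa3, Pdgfra and Dlk1 had log2 changes of -0.53, -0.52 and -0.55. Without the library labelled knockout replicate 1, 1 progenitor gene rose and 4 fell.

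Among the remaining lists, Trps1 fell in the mammary list, 1 of 10 (2 adjusted over the list alone; limma camera adjusted p = 0.0325, or adjusted p = 0.633 with an estimated correlation). Trps1 was not called without WT replicate 2 or 3 (edgeR, 0 of 10 called and 2 lower at an unadjusted p under 0.05), and 3 mammary genes fell without the library labelled knockout replicate 1. The mammary list's call ended without WT replicate 1 (0.0764) or 3 (0.0512) or the library labelled knockout replicate 2 (0.102) or 3 (0.22). Flt1 fell among 18 endothelial genes (2 adjusted over the list alone; limma camera adjusted p = 0.0606). Of the 18 edgeR called 0 without WT replicate 1, 2 or 3 or the library labelled knockout replicate 2, with 4, 4, 4 or 2 lower at an unadjusted p under 0.05, and 2 without replicate 3. Tyms fell among 28 proliferation genes (1 adjusted over the list alone; limma camera adjusted p = 0.444). Of the 28 edgeR called 0 without WT replicate 2 or 3, with 2 lower at an unadjusted p under 0.05, and 2 without the library labelled knockout replicate 2. Thbs1 and Timp1 fell among 30 matrix genes by either adjustment (limma camera adjusted p = 0.0793). Of the matrix genes edgeR called 0 without WT replicate 2 or 3 or the library labelled knockout replicate 2, with 2, 3 or 4 lower at an unadjusted p under 0.05, and 1 without the one labelled knockout replicate 3. In the Schwann cell list Mpzl2 and Pmp2 rose, 2 of 14 (3 higher and 1 lower adjusted over the list alone), and its median of -0.13 and mean of 0.20 differed in sign (limma camera adjusted p = 0.645). Only 1 Schwann gene was called without WT replicate 1, 2 or 3 or the library labelled knockout replicate 3, and 1 also fell without the one labelled knockout replicate 1. The fixed list of Ddx3y, Eif2s3y, Kdm5d and Uty had 0 calls among these 4 by either adjustment (limma camera adjusted p = 0.999).

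Genes around Hspb6 on chromosome 7 were called more often than genes elsewhere. Sbsn, a suprabasin secreted by epidermis that lies 190 kb from Hspb6 (30732674 to 30756134 on GRCm38), fell from 60.3 ± 6.59 to 10.3 ± 0.826 CPM (SD, n = 3 each; edgeR adjusted p = 2.02e-04), with 10.2, 9.57 and 11.2 CPM in the libraries labelled knockout replicates 1 to 3. Dmkn and Krtdap, also epidermal genes, fell by 1.83 and 2.13 on the log2 scale, and Ffar1 lies 307 kb away. Within 10 Mb, 29 of 235 tested genes were called, 12.3%, against 1190 of 15711 elsewhere, 7.57% (2-sided Fisher's exact test, odds ratio 1.72, 95% interval 1.12 to 2.56, p = 0.00924). Against the rest of chromosome 7 alone the odds ratio was 1.40 (95% interval 0.867 to 2.22, Fisher's exact test p = 0.142). Shares called over whole chromosomes ran from 5.1% on chromosome 8 to 9.72% on chromosome 7, apart from 41.2% on Y. Among the 29 calls Gm10662 and Gm5891 had the same mean and SD, so the test may count a signal more than once. Of 30 near neighbours fixed in advance, Cox7a1, Cox6b1 and Arhgap33 rose and Tbcb fell (4 and 4 adjusted over the list alone; limma camera adjusted p = 0.775). Leaving out WT replicate 2 or 3, edgeR called 0 of 31 neighbours, with 6 or 5 higher and 5 or 4 lower at an unadjusted p under 0.05. It called 1 higher and 2 lower without WT replicate 1, and 3 and 3 without the library labelled knockout replicate 1. Epidermis genes passed as a group (3 of 11 lower, Sbsn, Dmkn and Krtdap, by either adjustment; limma camera adjusted p = 0.0293, or adjusted p = 0.429 with an estimated correlation), and that call ended without WT replicate 1 (adjusted p = 0.0555), WT replicate 3 (0.112) or the library labelled knockout replicate 1 (0.119). Only 1 epidermis gene fell without WT replicate 1 or 3.

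**Figure D5:**
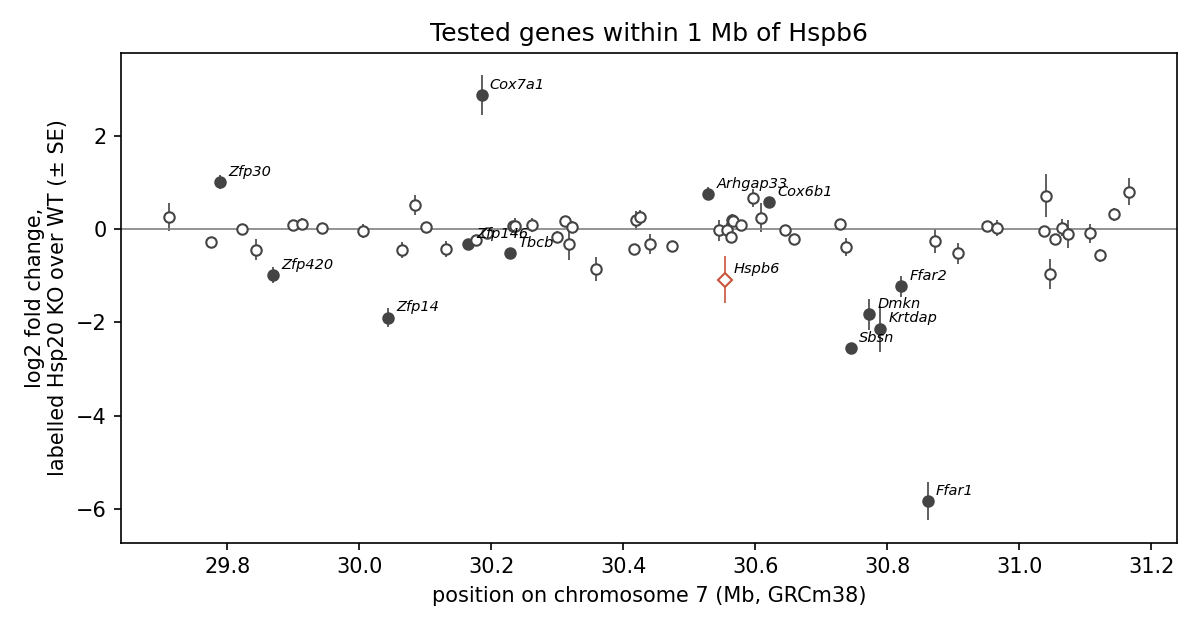
Log2 fold change of the libraries labelled Hsp20 KO over WT (vertical axis, bars give the SE) of the tested genes within 1 Mb of Hspb6 against their midpoint on chromosome 7 (horizontal axis, Mb on GRCm38); filled points passed an adjusted p of 0.05, and the open diamond is Hspb6. Ffar1 has the lowest value, at -5.83, and Cox7a1 the highest, at 2.87.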

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

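Thinning and the 1 Mb window were chosen after the data were seen. The 1223 calls kept their sign in every setting in which they were tested. The groups did not overlap for any of the 1223, so leaving out a library could hardly turn a sign. The kept signs are therefore no support for the calls. DESeq2 called 1136 genes higher and 1017 lower, against 676 and 547. A fold of at least 1.5 left 448 and 336, and an adjusted p under 0.1 gave 1250 and 1126. Other normalizations, filters, limma-voom, robust dispersions and thinning (563 and 474) kept these 2 totals within 1.5 times, though not the count of every list. Upper quartile normalization gave the widest range among scalings, 754 and 489. Leaving out single libraries gave 75 to 941 genes higher and 53 to 730 lower, lowest without WT replicate 3 and highest without the library labelled knockout replicate 1. Among the named genes' calls 63 were lost without WT replicate 2, 66 without WT replicate 3, 25 to 27 without WT replicate 1 or the one labelled knockout replicate 2 or 3, and 6 without the one labelled knockout replicate 1. Fewer samples leave fewer degrees of freedom, and the cause beyond that was not tested.

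The replicate block gave 226 genes higher and 169 lower, 19 lists and a log2 change of Hspb6 of -1.34, with 11 oxidative phosphorylation, 5 citric acid cycle, 4 fatty acid oxidation, 6 thermogenic, 9 lipogenic, 2 cholesterol and 3 adipocyte identity genes higher. Deviations of same-numbered libraries correlated at -0.038, 0.092 and -0.096, and those of differently numbered ones from -0.084 to 0.12, so no pairing by number was seen. With 3 libraries per group this cannot exclude a pairing. Not every library correlated best with its own number.

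Hspb6 ran from -1.99 (passed, adjusted p = 0.0221, without the library labelled knockout replicate 1) to -0.64 over left-out libraries, and passed in no other setting (edgeR, DESeq2 and limma-voom adjusted p from 0.121 to 0.409). Lists past the threshold fell from 18 to 0 with an estimated correlation and ran from 14 to 17 over left-out libraries. The odds ratio near Hspb6 was 1.81 within 5 Mb, 1.69 within 20 Mb and 2.98 within 1 Mb.

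Results that did not pass changed sign in places when a library was left out, and the cause was not tested. The log2 change of Lep ran from -0.330 to 0.0264 and that of Fbxo4 from -0.0512 to 0.132. Camera turned direction without a call in the turned setting, with limma camera adjusted p over left-out libraries from 0.102 to 0.821 for adipocyte identity, 0.0665 to 0.915 for heat shock genes, 0.00825 to 0.915 for matrix genes, 0.0324 to 0.886 for proliferation, 0.161 to 0.817 for Schwann genes and 0.815 to 0.946 for the list of 4 Y-linked genes. Matrix genes passed as lower without the library labelled knockout replicate 1 or 3, and also with the block (0.046), interferon genes passed as lower without replicate 1 (0.0158), and endothelial genes without WT replicate 3 (0.0469), without the library labelled knockout replicate 3 (0.00169) and with limma-voom (0.0356). Proliferation passed as higher without WT replicate 3. The Y-linked list also turned with DESeq2 size factors (0.989) and with the block (0.986).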

Other observations

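Genes in this paragraph and the next were chosen after their values were seen, as were all tests below except those of brown fat markers and of the splits; thinning itself was added after the data were seen. Pygl, glycogen phosphorylase, rose in the libraries labelled knockout from 179 ± 4.26 to 526 ± 95.03 CPM (SD, n = 3 each), and Ppp1r3b and Gbe1 rose 3.11-fold and 2.22-fold (edgeR quasi-likelihood adjusted p from 0.0023 to 0.00597). Gys2, a glycogen synthase, had a log2 change of 1.09 that did not pass (edgeR adjusted p = 0.0773), and no glycogen list was tested. Fasn, fatty acid synthase, rose from 4469 ± 847 to 18400 ± 4493 CPM (edgeR adjusted p = 0.00776), while Scd1 had a log2 change of 1.14 that did not pass (0.0737). Hlf and Tef, partners of Dbp, rose 3.91-fold and 2.46-fold. Mcpt9 rose beside Mcpt2, whereas the mast cell genes Mcpt4 and Cpa3 had log2 changes of -0.21 and -0.11 (edgeR adjusted p = 0.698 and 0.826).

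On the Y chromosome 14 of 34 tested genes were called, all lower, 41.2% against 7.57% elsewhere (2-sided Fisher's exact test, odds ratio 8.54, 95% interval 3.98 to 17.8, p = 7.02e-08). These include the multi-copy families of Rbmy, Sly and Ssty2, whose copies can share reads and are not independent. Plac9a, Plac9b, Tmem254a, Tmem254b and Tmem254c, also near-identical copies, fell by 2.06, 2.06, 1.59, 1.58 and 1.58 on the log2 scale. Nnt, a mitochondrial transhydrogenase whose sequence differs between C57BL/6 substrains, rose from 16.5 ± 0.472 to 31.1 ± 6.44 CPM (edgeR adjusted p = 0.0165), with no test of the substrain made here. A strain or substrain difference between the groups cannot be told apart from genotype. This limit holds for these genes and for the thermogenic, lipogenic, mitochondrial and clock genes alike.

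Hspb6 was near the WT level in the library labelled knockout replicate 1. A WT library under a knockout label would lie near WT over genes called without it, and its median log2 position was 0.582 (0 at WT, 1 at the other libraries labelled knockout; quartiles 0.345 and 0.812 over 545 genes), which argues against that label error. For a mixture of WT and knockout RNA, the linear position of those genes (median 0.528, lower quartile 0.286) was not clearly apart from that of Hspb6 (0.194, at most 0.38 against a single WT library), but 14 genes within 1 Mb of Hspb6, read in a further test, had a median position of 0.99 with a lower quartile of 0.567, which argues against a mixture. Muscle RNA is also argued against, since the log2 excess of this library over the others labelled knockout was -0.592 for muscle genes and 1.82 for Hspb6. What sets this library apart stays open.

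Thermogenic, lipogenic and mitochondrial lists were higher in the libraries labelled knockout. For lower depth, the largest fall of a median was 0.01 after thinning to the smallest library. All 5 lists stayed past the threshold of camera at its preset correlation, while unthinned 0 lists passed with an estimated one. The lists thus stayed higher at equal library totals. Thinning keeps the expected CPM of a gene, however, so a median could hardly fall whatever the cause. It therefore cannot decide whether lower depth plays a part. The first bound written, medians within 0.1 in both directions, was missed because the thermogenic median went up from 1.53 to 1.71. A larger share of adipocyte RNA as the whole cause is argued against by adipocyte identity genes, whose median lay -0.505 from that of the citric acid cycle. In the libraries labelled knockout replicates 1 to 3 the identity medians lay -0.0558, -0.0409 and 0.394 from the WT mean, against 0.36, 0.714 and 0.793. The gene permutation p of 0.00067 treats genes as independent, though their estimated correlations were 0.374 and 0.678. It does not measure the spread between mice and is no support. Interscapular brown fat cannot be told apart, as 0 of its markers Zic1 and Lhx8 rose (edgeR adjusted p = 0.772 and 0.61) at counts too low to exclude a small share. A different clock phase at tissue collection cannot be told apart from genotype: Dbp and its group lay 2.71 above Arntl and its group on the log2 scale, but these groups were picked after their directions were seen, so the value is no support, and no collection time was at hand.

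Calls were concentrated near Hspb6. Within 1 Mb 13 of 66 tested genes were called, 19.7%, against 9.47% between 1 and 10 Mb (2-sided Fisher's exact test, odds ratio 2.34, 95% interval 0.965 to 5.58, p = 0.0455). The window was picked from the pattern itself, so this restates it, and linked alleles of another strain cannot be told apart from a local effect of the targeted allele. The interval of the odds ratio includes 1. The calls within 1 Mb include Cox7a1 and Cox6b1, members of the thermogenic and oxidative phosphorylation lists, most of whose called genes lie elsewhere. Epidermal tissue in the WT samples is argued against, since the 8 other epidermis genes had a median of -0.155. Both linked alleles and such a local effect stay open, untested.

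For the number of called genes, 1 of the 10 splits of the libraries into 3 and 3, the real one, gave 1223 genes, and the highest of the others gave 1. With 10 splits a share under 0.05 cannot be reached.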
